A study of Mus musculus with 12 samples.

How the data were processed

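Gene expression was measured on Illumina mouse bead arrays in 12 samples of endothelial-enriched RNA, each pooled from 3 carotid arteries per the labels. The deposited table of unprocessed values holds, per the file headers, an intensity and a detection p-value for each of 45281 probes and each sample. The authors exported these with GenomeStudio 2010.3 per the labels. A deposited table of normalized intensity values was also read: its columns share 1 distribution, so the authors' values are quantile-normalized intensities on a linear scale, as judged from the values. It served as an alternative only. The labels state an age of 9 weeks. The samples were run on 2 microarrays per the series description, but which sample was on which was not given in the sources used here, so no term for it was fitted.

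Samples were grouped by the labels into saline LCA, saline RCA, 5Aza LCA and 5Aza RCA, with 3 in each. The numbers in the titles and in the descriptions differ for some samples; titles were used for naming. The labels do not say whether equal numbers mark arteries of the same mice, so arteries were compared without pairing.

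From the unprocessed intensity values, background was corrected by the normal-exponential model with negative control statistics inferred from the detection p-values (limma's neqc, offset 16), followed by quantile normalization and log2. Probes were kept when detected at detection p under 0.05 on all 3 samples of at least 1 group, which left 21979. Of the 45281 probes, 34885 carried 1 gene symbol, 18 several and 10378 none, and 34807 matched the gene identifiers of the reference table that supplied current symbols. Of the probes kept, 18150 had 1 symbol, and the brightest probe stood for each of the 4659 genes with more than 1, giving 10596 genes. Detected probes ranged from 21443 to 23251 per array. The ratio of the 75th percentile of intensity to the median was 1.34 to 1.48, and median intensities were 83.8 to 88.9.

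A linear model with 1 mean per group was fitted to all 12 samples with limma 3.58.1 in R 4.3.3, and 7 contrasts were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment within each contrast. Genes with adjusted p under 0.05 were called. SE is that of the moderated test. A gene counts as detected on an array where any of its probes was, not only the brightest. Where no array of the dimmer group detected a gene, its change is given only as a bound ("at least"). Sets of genes written before the data were examined were tested with camera (preset inter-gene correlation 0.01), with 29 of 33 lists holding the 5 tested members required. Adjusted p-values for lists were computed within each contrast, and medians are of the members' log2 fold changes. One list was recalled from the study. Results were compared with camera with an estimated correlation and with fry, a rotation test of whether a list's genes move on balance in 1 direction. The correlation of the flow effects was set against data simulated with no effect and independent genes. Opposite calls were set against data simulated with the average flow effect and no 5Aza effect, with noise either independent between genes or rebuilt as random mixtures of the 3 departures of each group's arrays from their mean. The mixtures overstate how far genes vary together, and this test was chosen after the data were seen.

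The genes to be named were fixed by a rule before the data were examined. In each comparison they are the 10 largest increases and the 10 largest decreases among called genes whose groups do not overlap, or, where no gene passed, the 3 highest and 3 lowest by moderated statistic. In each list they are the members past the threshold, up to 4 with the smallest adjusted p, or otherwise up to 3 with the smallest p, and every gene of the list recalled from the study. For opposite calls they are the 10 with the largest smaller change. Of the genes that the rule names for flow under saline and for average flow, 1 gene is not reported here.

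Alternatives covered the starting values, background correction, scaling between arrays, the filter, probes per gene, the variance prior, array weights, the samples in the fit, replicate blocks, set tests, a minimum fold of 1.5 and leaving out each array. With 1 array left out, the remaining pair is assumed to vary like the other groups. The macrophage or adipocyte level as a covariate was added after the data were seen. For the list that supplies the level, such a fit removes the list's own shift by design. Its value within that list's range over the alternatives is therefore no test. In the main pipeline tested on simulated data, 42% of genes shifted by log2 1 and 85% of genes shifted by log2 2 were recovered among 100 of each, with 4 false calls in the comparison of saline LCA with saline RCA and 0 to 7 in the other comparisons. The simulated genes varied independently and with 1 spread per gene in all groups, unlike the arrays, so error rates on the real data may differ. Among 29 simulated lists, camera called the 1 shifted list and 1 unshifted list. Probes without a single symbol were left out of the gene tests.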

Results

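RNA enriched for endothelial cells was measured on Illumina bead arrays after partial ligation of the mouse left carotid artery, an operation that closes 3 of the 4 caudal branches and leaves slow, disturbed flow in that vessel. Male C57Bl6 mice received saline or 5-aza-2'-deoxycytidine (5Aza, an inhibitor of DNA methyltransferases, 0.2 mg/kg/day) for 3 weeks, and the ligated left artery (LCA) and the unligated right artery (RCA) were taken 7 days after surgery. Each of the 12 samples was RNA flushed from the lumen of 3 pooled arteries, and the 4 groups (saline LCA, saline RCA, 5Aza LCA and 5Aza RCA) held 3 samples each, numbered here as in their titles. Between 21443 and 23251 of the 45281 probes were detected per array, and 10596 genes were tested. The number of arrays per group limits the precision of every comparison, and each p-value measures only the spread between these pools. What is called a flow effect here is the difference between ligated left and unligated right arteries. No group held sham-operated or unligated left arteries. That difference therefore cannot be told apart from effects of the surgery, of the side or of the cell types in the flushed RNA.

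The ligated arteries of saline mice varied most. The root mean variance within a group was 0.51 on the log2 scale in saline LCA, against 0.33 in saline RCA, 0.37 in 5Aza LCA and 0.36 in 5Aza RCA. The model gave each gene 1 spread for all 4 groups. SEs and p-values of comparisons with saline LCA therefore tend to be too small. With only the compared groups in the fit, and so fewer samples, 135 genes were called by flow under saline in place of 1227. Saline LCA 1 correlated over genes at 0.857 and 0.856 with saline LCA 2 and 4, which correlated at 0.971 with each other. On the first principal component, saline LCA 1 fell at -1.24, close to the 5Aza LCA samples (0.08 to 11.9), whereas saline LCA 2 and 4 fell at 67.7 and 68.4. On the second component it fell at -7.60, between the 5Aza LCA samples (-32.6 to -20.8) and saline LCA 2 and 4 (12.9 and 13.0).

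**Figure D1:**
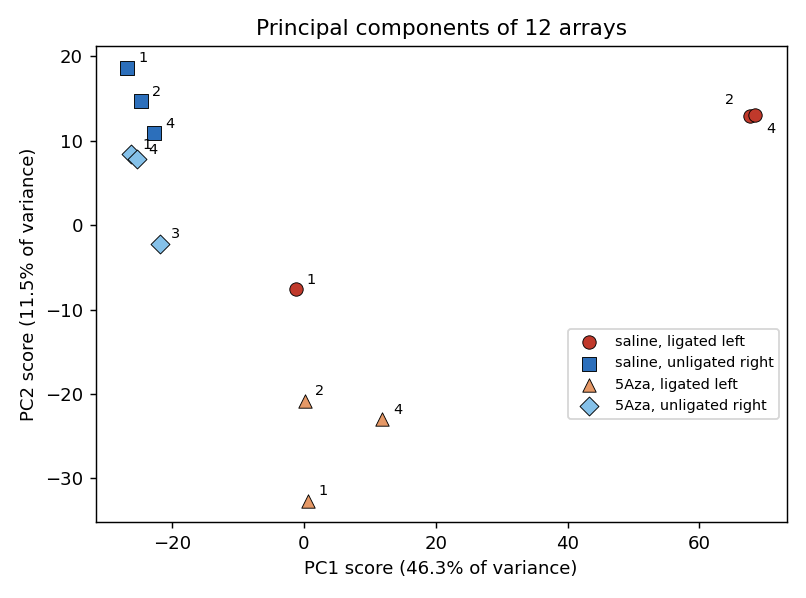
Principal components of the 12 arrays from the log2 levels of the tested genes, with the share of variance on each axis (46.3% and 11.5%) and 1 point per sample. The unligated samples lie between -26.8 and -21.8 on the first component.

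The question of which genes disturbed flow alters was addressed by comparing saline LCA with saline RCA. Genes of macrophages were among those that rose most: Aif1, a calcium-binding protein of macrophages, averaged 9.85 ± 0.91 in saline LCA and 4.57 ± 0.31 in saline RCA (log2 level, mean ± SD, n = 3 each). Its log2 fold change in limma was 5.28 (SE 0.39, adjusted p = 6.81e-05), with the gene detected on 2 of the 3 saline RCA arrays. Tyrobp, the signalling adaptor of myeloid receptors, rose by 4.71 (SE 0.57, adjusted p = 0.00126, detected on 1 of the 3 saline RCA arrays), and C1qb, a chain of complement C1q, was at least 16.6-fold higher (adjusted p = 0.00209). The phagocyte receptor gene Clec7a rose by 3.98 (SE 0.43, adjusted p = 0.000836, detected on 1 saline RCA array), and Mpeg1, a perforin-like protein of macrophages, rose by 3.95 (SE 0.53, adjusted p = 0.00218, detected on 1 saline RCA array). The other named increases were those of the lectin Clec10a (3.99, adjusted p = 0.0116), the lysosomal protein Laptm5 (4.42, adjusted p = 0.0121), the lysozyme Lyz1 (3.97, adjusted p = 0.02), the collagenase Mmp13 (4.08, adjusted p = 0.0139) and the beta-globin Hbb-bs (4.19, adjusted p = 0.0347). Without saline LCA 1 the log2 fold changes were 5.38 for Tyrobp, 5.16 for Mmp13, 4.87 for Clec10a, 4.77 for Lyz1 and 4.56 for Mpeg1, and Mmp13 stood at 3.48 without saline LCA 2. Without saline RCA 1 or 4, those of Laptm5 were 3.44 and 5.32 and those of Lyz1 were 3.24 and 4.84. Probes for Lyz1 and Hbb-bs may not tell near-identical gene copies apart, which was not checked.

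The 10 largest decreases in the ligated artery were led by Prrt4. This gene, which encodes a proline-rich transmembrane protein, averaged 4.23 ± 0.07 in saline LCA and 8.65 ± 0.18 in saline RCA (n = 3 each) and was at least 18.2-fold lower in limma (adjusted p = 2.46e-07), since no saline LCA array detected it. Klk10, a kallikrein-related protease, averaged 5.00 ± 1.30 against 8.93 ± 0.22 (n = 3 each), a log2 fold change of -3.94 (SE 0.47, adjusted p = 0.00126, detected on 1 of the 3 saline LCA arrays). Klk8, of the same protease family, changed by -3.26 (adjusted p = 0.0222) and the aldehyde dehydrogenase Aldh3a1 by -3.24 (SE 0.43, adjusted p = 0.00216). The matrix genes Col4a3 (-3.24, adjusted p = 0.0188), Mfap5 (-2.99, SE 0.29, adjusted p = 0.000444) and Fndc1 (-2.96, SE 0.25, adjusted p = 0.000176) fell as well. Mfap5 and Fndc1 were detected on 1 saline LCA array each. The junction gene Plekha6 (-3.17, adjusted p = 0.00328) and the antiprotease Serpina1a (-3.09, adjusted p = 0.0069) were also among the 10 largest decreases. In saline LCA 1, Klk8 (8.31) and Col4a3 (7.85) lay nearer to the unligated samples than in saline LCA 2 and 4. Without that array the log2 fold changes were -4.69 for Klk10, -4.49 for Klk8, -4.40 for Col4a3, -3.87 for Aldh3a1 and -3.78 for Serpina1a, and without saline LCA 2 Klk8 stood at -2.52 and Col4a3 at -2.58. Probes for Serpina1a may not tell it from its near-identical neighbours, which was not checked. In all, 1227 genes passed adjusted p under 0.05, 562 higher and 665 lower in the ligated artery.

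**Figure D2:**
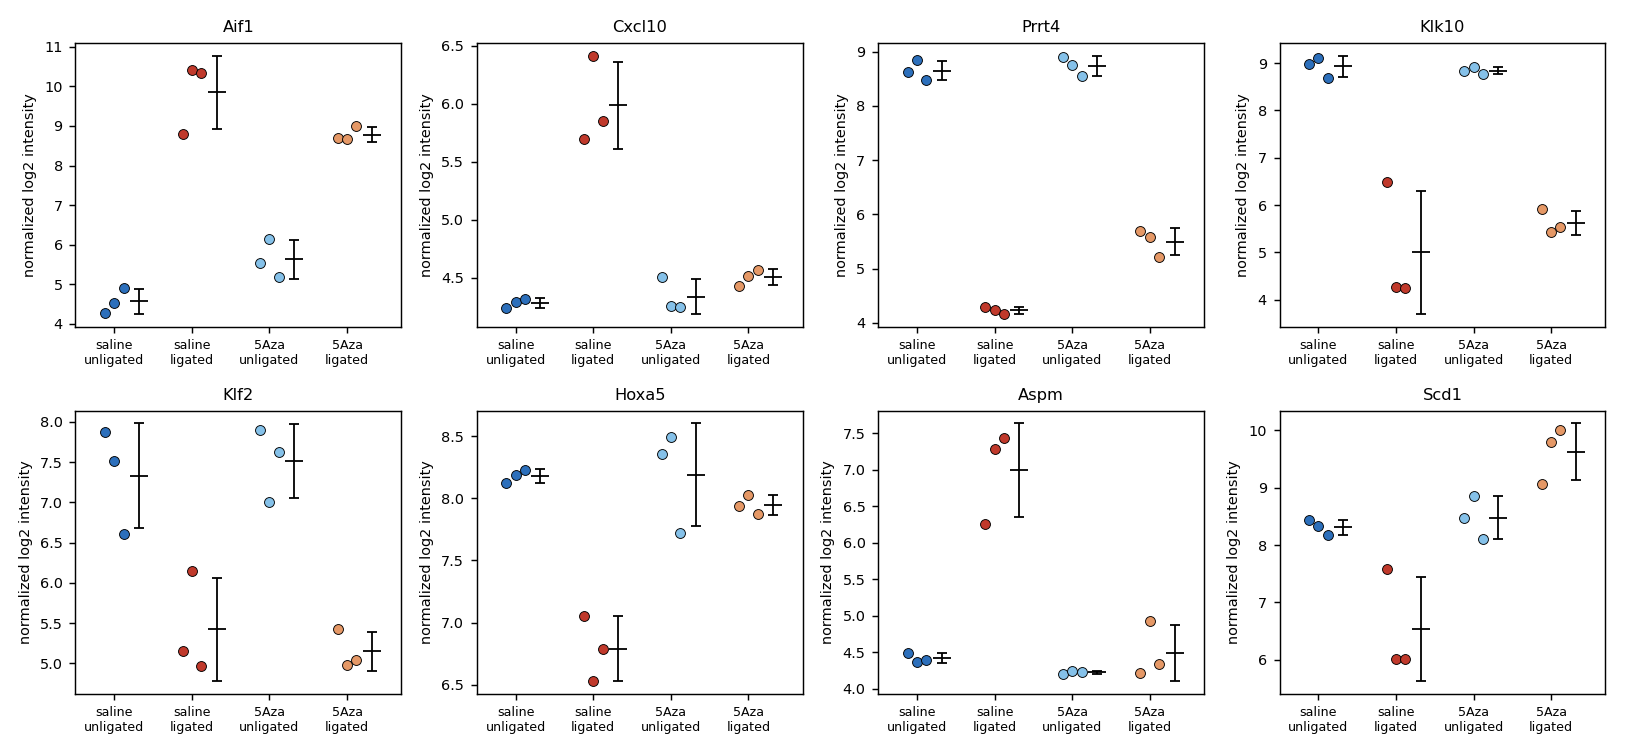
Log2 level of 8 genes named in the text in each sample of the 4 groups, with points for samples and bars for the group mean ± SD (n = 3). Aif1 averaged 9.85 in saline LCA and 4.57 in saline RCA, and Klf2 averaged 5.14 in 5Aza LCA and 7.51 in 5Aza RCA.

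Many macrophage markers rose in the ligated artery of saline mice. Of 20 macrophage and monocyte markers, 17 were higher, 0 were lower and 3 did not pass (19 higher when adjusted over the list alone). The median log2 fold change was 3.55, or 3.38 with 6 members at their bounds. Its camera test gave adjusted p = 3.2e-17, and adjusted p = 0.196 with an estimated correlation (4.05e-22 to 0.689 over all alternatives). The 0.689 came with the list's own level as a covariate, where the loss was fixed in advance. Genes of inflammation and adhesion shifted up by a median of 0.69 (adjusted p = 4.77e-05). This was the only list called with an estimated correlation (adjusted p = 0.0381, the highest over all alternatives). Of its members, 6 of 18 were higher, 0 lower and 12 not past (9 higher when adjusted over the list alone). Its T-cell chemokines Cxcl10 and Ccl5 were at least 2.8-fold (adjusted p = 0.000934) and at least 10.2-fold higher (adjusted p = 0.00205), the cytokine Il1b at least 7.13-fold (adjusted p = 0.0174), and the chemokine Cxcl12 rose by 1.33 (SE 0.32, adjusted p = 0.0255). Fcer1g, an immunoglobulin receptor chain of the macrophage list, was at least 11.6-fold higher (adjusted p = 0.00205).

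Of 5 neutrophil markers, 3 were higher and 2 did not pass (3 higher when adjusted over the list alone). Their median was 1.22 (1.17 with bounds, adjusted p = 0.0105, and adjusted p = 0.339 with an estimated correlation, 0.00125 to 0.881 over the alternatives). The higher ones were the calcium-binding alarmin S100a9 (at least 11.6-fold, adjusted p = 0.0154), the chemokine receptor Cxcr2 (at least 2.24-fold, adjusted p = 0.0366) and the chitinase-like Chil3 (1.22, adjusted p = 0.0407). Saline LCA 2 and 4 carried most of the neutrophil rise, with list levels of 6.36 and 6.27. Saline LCA 1 stood at 4.88, against 4.40 to 4.53 in saline RCA. Of 8 erythroid and platelet markers, the platelet integrin Itgb3 (at least 1.38-fold, adjusted p = 0.0237) and platelet factor Pf4 (2.87, adjusted p = 0.0448) were higher and 6 did not pass (3 higher when adjusted over the list alone). Their median was 0.91 (0.68 with bounds, adjusted p = 0.0484, and adjusted p = 0.347 with an estimated correlation, 0.0244 to 0.881 over the alternatives). Leaving out any of 8 arrays ended this call, with adjusted p from 0.0506 without saline LCA 2 to 0.0764 without saline RCA 2.

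Several of the genes that steady flow maintains in endothelium fell. Of 22 such atheroprotective genes, 12 were lower, 1 was higher and 9 did not pass (15 lower and 2 higher when adjusted over the list alone). The median was -1.03 (adjusted p = 1.07e-05, and adjusted p = 0.196 with an estimated correlation, 8.18e-08 to 0.295 over the alternatives). Klk10 and the flow-induced transcription factor Klf4 (-1.76, adjusted p = 0.00687) were among them. Of 3 further members named after their values were seen, the transcription factor Klf2 (-1.91, adjusted p = 0.0134) and the endothelial nitric oxide synthase Nos3 (-1.89, adjusted p = 0.0148) fell, and the kinase gene Prkca, the only higher member, rose by 1.38 (adjusted p = 0.0166). Of 24 endothelial markers, 7 were lower, 0 were higher and 17 did not pass (11 lower and 1 higher when adjusted over the list alone). The median was -0.44 (adjusted p = 0.00879, and adjusted p = 0.125 with an estimated correlation, 0.000106 to 0.125 over the alternatives). These included the adhesion molecule Icam2 (-1.58, adjusted p = 0.00126), the angiopoietin receptor Tek (-1.27, adjusted p = 0.00619), the adrenomedullin receptor partner Ramp2 (-0.88, adjusted p = 0.0137) and von Willebrand factor, Vwf (-0.93, adjusted p = 0.0147).

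Homeobox genes shifted downward as a list. The HOX list had a median of -0.48 over 13 genes (adjusted p = 0.0304, and adjusted p = 0.196 with an estimated correlation, 0.00145 to 0.205 over the alternatives). Hoxa5 (-1.39, SE 0.22, adjusted p = 0.00524) and Hoxa10 (-1.07, adjusted p = 0.0121) were lower, and 11 did not pass (3 lower when adjusted over the list alone). The call ended without saline LCA 1 (adjusted p = 0.201) and without saline RCA 1 (adjusted p = 0.0538). Another list held 9 genes recalled from the study itself, which chose them on these samples, so its counts are not independent evidence. Neither is Hoxa5 in the HOX list, as it is among these 9 genes. All 9 had negative values, and 5 of them passed (9 when adjusted over the list alone): Hoxa5, the BMP receptor Acvrl1 (-1.28, adjusted p = 0.00953), Tmem184b (-1.12, adjusted p = 0.018), the junction gene Pkp4 (-0.92, adjusted p = 0.0364) and the transcription factor Klf3 (-0.86, adjusted p = 0.0462). The chemerin receptor Cmklr1 (-1.61, adjusted p = 0.114), the adaptor Dok4 (-1.17, adjusted p = 0.0574), the growth factor antagonist Spry2 (-0.96, adjusted p = 0.0666) and the zinc finger gene Zfp46 (-0.86, adjusted p = 0.0514) did not pass. The list's median was -1.12 (adjusted p = 1.07e-05, and adjusted p = 0.219 with an estimated correlation, 1.26e-07 to 0.347 over the alternatives).

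Genes of cell division and of oxidative stress also shifted upward with flow under saline. Of 23 cell cycle genes, 6 were higher, 0 were lower and 17 did not pass (12 higher when adjusted over the list alone). The list's median was 0.92 (adjusted p = 1.35e-06, and adjusted p = 0.339 with an estimated correlation, 1.6e-08 to 0.339 over the alternatives). Most of the cell cycle rise came from saline LCA 2 and 4, with list levels of 7.29 and 6.78. Saline LCA 1 stood at 5.95, closer to every saline RCA sample than to saline LCA 2 or 4. The survivin gene Birc5 (2.06, SE 0.34, adjusted p = 0.00665), the spindle gene Prc1 (2.07, adjusted p = 0.0121), the mitotic kinase Aurka (2.21, adjusted p = 0.0213, detected on 2 of the 3 saline RCA arrays) and the topoisomerase Top2a (at least 2.22-fold, adjusted p = 0.0306) rose. Of 19 oxidative stress genes, 5 were higher, 1 was lower and 13 did not pass (6 higher and 2 lower when adjusted over the list alone). Its median was 0.33 (adjusted p = 0.027, and adjusted p = 0.331 with an estimated correlation, 0.0145 to 0.509 over the alternatives), and the call ended without saline RCA 2 (adjusted p = 0.0557). The phagocyte oxidase genes Cybb (3.00, adjusted p = 0.0108) and Ncf1 (at least 1.65-fold, adjusted p = 0.0241), the peroxidase Gpx1 (0.82, adjusted p = 0.0231) and the thioredoxin reductase Txnrd1 (1.17, adjusted p = 0.0326) rose. The extracellular dismutase Sod3, chosen here after its values were seen as the only lower member, fell by 2.25 (adjusted p = 0.046).

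The number of genes called by flow under saline rested on single arrays. Without saline LCA 1 it was 3114, which included 1209 of the 1227 genes, whereas it was 179 without saline LCA 2, 208 without saline LCA 4, 282 without saline RCA 2, 334 without saline RCA 1 and 391 without saline RCA 4. Of the 20 genes with the largest changes, 12 stayed called without saline LCA 2, 13 without saline LCA 4, 14 without saline RCA 2, 15 without saline RCA 1 and 17 without saline RCA 4. With each array's macrophage level as a covariate, of whose variance 83.6% lay between the groups, 2 genes passed.

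**Figure D3:**
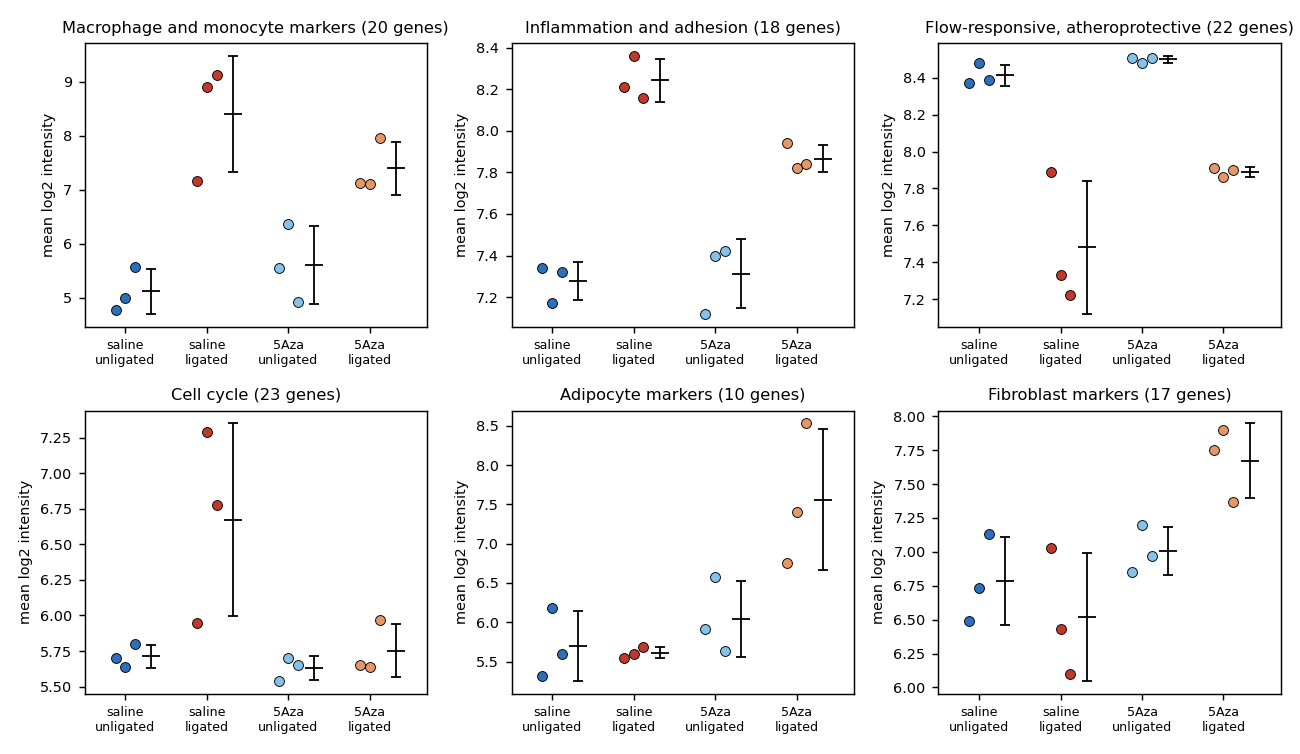
Mean log2 level of 6 gene lists in each sample of the 4 groups, with points for samples and bars for the group mean ± SD (n = 3). The macrophage list ran from 7.17 to 9.13 in saline LCA and from 7.10 to 7.96 in 5Aza LCA, and the adipocyte list ran from 5.55 to 5.69 and from 6.75 to 8.53.

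Whether flow altered the same genes in mice given the inhibitor was asked by comparing 5Aza LCA with 5Aza RCA. Several genes of macrophages were among the largest increases again, with Aif1 at 8.79 ± 0.18 in 5Aza LCA and 5.62 ± 0.49 in 5Aza RCA (n = 3 each), a log2 fold change of 3.16 (SE 0.39, limma adjusted p = 0.00717). The macrophage elastase Mmp12 rose by 3.34 (SE 0.52, adjusted p = 0.0229) and Tyrobp by 3.14 (SE 0.57, adjusted p = 0.0427), each detected on 1 of the 3 5Aza RCA arrays. Clec7a and the immunoglobulin receptor Fcgr4 were at least 4.15-fold (adjusted p = 0.0456) and at least 4.06-fold higher (adjusted p = 0.0396). Ces1d (3.18, SE 0.61, adjusted p = 0.0487), a lipase of fat cells, the lipogenic regulator Thrsp (1.96, SE 0.27, adjusted p = 0.0132) and the autophagy gene Depp1 (2.63, SE 0.31, adjusted p = 0.0062) rose, Thrsp and Depp1 with detection on 1 5Aza RCA array each. The Tek ligand Angpt2 rose by 1.90 (SE 0.30, adjusted p = 0.0229), and Ccn2, a matrix-associated growth factor, by 1.87 (SE 0.33, adjusted p = 0.042).

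Prrt4 fell with flow under 5Aza as well, from 8.73 ± 0.18 to 5.50 ± 0.26 (n = 3 each), a log2 fold change of -3.24 (SE 0.18, limma adjusted p = 8.63e-06). Klk10 averaged 5.63 ± 0.25 in 5Aza LCA and 8.84 ± 0.07 in 5Aza RCA (log2 fold change -3.21, SE 0.47, adjusted p = 0.0183), and Klf2 averaged 5.14 ± 0.24 against 7.51 ± 0.46 (log2 fold change -2.36, SE 0.38, adjusted p = 0.0229). The vesicle gene Syt7 (-2.07, SE 0.17, adjusted p = 0.000356), the matrix genes Fndc1 (-1.84, adjusted p = 0.0128) and Mfap5 (-1.64, adjusted p = 0.042) and the noncoding RNA Miat (at least 2.85-fold lower, adjusted p = 0.012) fell. Nxpe2 (-1.61, adjusted p = 0.0427), the transcriptional repressor Bhlhe40 (-1.57, adjusted p = 0.0483) and the ion transporter Slc12a5 (-1.55, adjusted p = 0.0427) were the remaining named decreases. In all, 48 genes passed, 25 higher and 23 lower. The count was 4 without 5Aza RCA 1, 9 without 5Aza LCA 4, 16 without 5Aza LCA 2, 17 without 5Aza RCA 4, 18 without 5Aza LCA 1, and 22 without 5Aza RCA 3, saline LCA 2 or saline RCA 1. It was 24 without saline RCA 2 or saline RCA 4, 30 without saline LCA 4 and 286, with all 48 among them, without saline LCA 1. Of the 20 genes with the largest changes, 3 stayed called without 5Aza RCA 1, 5 without 5Aza LCA 4, 7 without 5Aza RCA 4, 8 without 5Aza LCA 2 and 11 to 13 without any other array but saline LCA 1.

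In camera, 12 of 29 lists shifted with flow under 5Aza, and 0 of them with an estimated correlation. Macrophage markers had a median of 1.87 (1.80 with bounds, adjusted p = 6.03e-13, and adjusted p = 0.263 with an estimated correlation, 9.2e-19 to 0.907 over the alternatives). Of these, 2 of 20 were higher and 18 did not pass (11 higher when adjusted over the list alone). The 0.907 came with the list's own level as a covariate. Inflammation genes shifted by 0.33 (0.27 with bounds, adjusted p = 0.000354, and adjusted p = 0.0669 with an estimated correlation, 4.44e-05 to 0.0669 over the alternatives). Only the vasoconstrictor peptide gene Edn1 passed (1.64, SE 0.29, adjusted p = 0.042), and 17 did not (3 higher when adjusted over the list alone). Immediate early genes shifted by 0.50 (0.46 with bounds, adjusted p = 0.00273, and adjusted p = 0.363 with an estimated correlation, 3.82e-05 to 0.363 over the alternatives). Of these 19 genes the transcription factor Fosb passed (1.73, SE 0.32, adjusted p = 0.0427, 2 higher when adjusted over the list alone). Without 5Aza LCA 1 the immediate early list had adjusted p = 0.138.

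Atheroprotective genes had a median of -0.36 (adjusted p = 5.21e-05, and adjusted p = 0.263 with an estimated correlation, 1.22e-06 to 0.319 over the alternatives). Klk10 and Klf2 were lower, and 20 of 22 did not pass (3 lower when adjusted over the list alone). Endothelial markers had a median of -0.31 (adjusted p = 0.00273, and adjusted p = 0.083 with an estimated correlation, 0.000468 to 0.083 over the alternatives). Icam2 was lower (-1.04, SE 0.19, adjusted p = 0.0427), and 23 did not pass (4 lower and 1 higher when adjusted over the list alone). Notch pathway genes had a median of -0.21 over 15 members (adjusted p = 0.0483, and adjusted p = 0.263 with an estimated correlation, 0.0126 to 0.263 over the alternatives). None of them passed, in the list alone either, the nearest being the receptors Notch4 (-0.86, adjusted p = 0.23) and Notch1 (-0.82, adjusted p = 0.257) and the gap junction gene Gja5 (-0.47, adjusted p = 0.279). That call ended without any of 6 arrays, with adjusted p from 0.0509 without saline LCA 2 to 0.196 without 5Aza RCA 4. The 9 genes recalled from the study, not independent evidence on these samples, had a median of -0.39 (adjusted p = 0.0076, and adjusted p = 0.363 with an estimated correlation, 0.00123 to 0.963 over the alternatives). In limma 0 of them passed, in the list alone either, the smallest adjusted p being 0.293 for Tmem184b (-0.66).

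Adipocyte and fibroblast markers shifted upward as lists in the ligated artery of 5Aza mice. The adipocyte list shifted by a median of 1.71 over 10 genes (adjusted p = 4.66e-05, and adjusted p = 0.263 with an estimated correlation, 1.83e-07 to 0.995 over the alternatives). The 0.995 came with the list's own level as a covariate. Over all genes 0 members passed, and 6 when adjusted over the list alone. Adiponectin, Adipoq (2.28, adjusted p = 0.0983), the lipase Lpl (2.94, adjusted p = 0.184) and the lipid droplet gene Plin4 (1.59, adjusted p = 0.239) came nearest. The fibroblast list shifted by 0.73 over 17 genes (adjusted p = 0.000406, and adjusted p = 0.331 with an estimated correlation, 4.17e-05 to 0.331 over the alternatives). Its only member past over all genes, Mfap5, fell (6 higher and 2 lower when adjusted over the list alone). Erythroid and platelet markers had a median of 1.10 (adjusted p = 0.00262, and adjusted p = 0.331 with an estimated correlation, 6.32e-05 to 0.331 over the alternatives). None of the 8 passed, in the list alone either. The haemoglobin genes Hbb-b2 (2.46, adjusted p = 0.212) and Hba-a1 (2.65, adjusted p = 0.302) and the chemokine Ppbp (1.88, adjusted p = 0.368) came nearest. Without 5Aza LCA 1 this list had adjusted p = 0.0541.

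None of 19 respiratory chain genes passed, in the list alone either. Their median was 0.22 (adjusted p = 0.0131, and adjusted p = 0.45 with an estimated correlation, 0.000577 to 0.803 over the alternatives). Sdha (0.60, adjusted p = 0.289), Uqcrc1 (0.47) and Cox7b (0.32), subunits of complexes of that chain, came nearest. Without 5Aza LCA 4 the list had adjusted p = 0.468. Oxidative stress genes had a median of 0.06 and a mean of 0.32 (adjusted p = 0.0149, and adjusted p = 0.331 with an estimated correlation, 0.00548 to 0.944 over the alternatives). None of the 19 passed, in the list alone either. The dehydrogenase gene Xdh (at least 1.34-fold, adjusted p = 0.198), the peroxidase Gpx3 (1.95, adjusted p = 0.199) and Cybb (1.74, adjusted p = 0.227) came nearest. The call ended without 5Aza LCA 4 (adjusted p = 0.0918) and without 5Aza RCA 4 (adjusted p = 0.0753).

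The flow effects under saline and under 5Aza ran in the same direction for most genes. Over the 10596 genes, which are not independent replicates, they correlated at 0.575, and the slope of the 5Aza effect on the saline effect was 0.368. In data simulated with no effect and independent genes the correlation averaged -0.00183 (SD 0.014). That spread does not cover genes that vary together, and other splits of the samples reached a correlation of 0.46 in size. Without 5Aza LCA 4 the correlation was 0.493. The 26 genes called in both comparisons all moved the same way, where 2.77 shared calls in the same direction are expected from independent lists. Of the 1227 genes called under saline, 1111 kept their sign under 5Aza, and 1198 had a smaller change there, as chosen genes tend to in any other comparison. Of the 48 genes called under 5Aza, 43 had the same sign under saline and 26 a smaller change, with a slope of 0.897 of the saline effect on the 5Aza effect over all genes.

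What the inhibitor did in the artery with disturbed flow was asked by comparing 5Aza LCA with saline LCA. Among the genes higher in the ligated arteries of 5Aza mice were some of fat cells and lipid synthesis: the desaturase Scd1 averaged 9.63 ± 0.49 in 5Aza LCA and 6.54 ± 0.91 in saline LCA (n = 3 each), a log2 fold change of 3.09 (SE 0.40, limma adjusted p = 0.0098). Ces1d was at least 15.4-fold higher (adjusted p = 0.0212), Adipoq at least 6.21-fold (adjusted p = 0.0481) and Thrsp at least 3.59-fold (adjusted p = 0.0098), and Gpd1, a glycerol phosphate dehydrogenase, rose by 2.33 (SE 0.39, adjusted p = 0.0325, detected on 1 of the 3 saline LCA arrays). The connective tissue genes Clec3b (3.21, SE 0.49, adjusted p = 0.0301), Abi3bp (2.29, SE 0.43, adjusted p = 0.0481) and Coch (1.93, SE 0.30, adjusted p = 0.0321, detected on 1 saline LCA array) rose. The kelch gene Klhdc8b (2.28, SE 0.38, adjusted p = 0.0325) and the amylase Amy2a5 (2.33, SE 0.38, adjusted p = 0.0325, detected on 1 saline LCA array), whose near-identical copies may not be told apart, rose too. Clec3b stood at 3.91 without saline LCA 1. Adipoq stood at 6.04, 6.83 and 8.43 in 5Aza LCA 1, 2 and 4, so its bound leans on the last. Its log2 fold change went from 2.83 to 2.16 without 5Aza LCA 4, which lies below that bound. Its call ended without 9 of the 12 arrays in turn, with adjusted p from 0.0684 without 5Aza LCA 4 to 0.201 without saline LCA 2. In all, 49 genes passed, 31 higher and 18 lower. When arrays were scaled to a common median instead, 37 genes passed, 14 of them higher and 23 lower. The count was 0 with only the compared groups in the fit or with title numbers across groups as a block. With array weights it was 2258.

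Among the genes lower in the ligated arteries of 5Aza mice were some of cell division and of immune cells. The mitotic spindle gene Aspm averaged 4.49 ± 0.39 in 5Aza LCA and 6.99 ± 0.64 in saline LCA (n = 3 each), a log2 fold change of -2.50 (SE 0.29, limma adjusted p = 0.0098, detected on 1 of the 3 5Aza LCA arrays), and Birc5 changed by -2.10 (SE 0.34, adjusted p = 0.0325). The inhibitory receptors Lair1 (-1.93, SE 0.23, adjusted p = 0.0098) and Lilr4b (-2.21, adjusted p = 0.0496) and the signalling gene Dock10 (-1.61, adjusted p = 0.0418) fell, each detected on 1 5Aza LCA array. The myeloid kinase Fgr (-2.10, adjusted p = 0.0374), the LPS co-receptor subunit Ly86 (-2.01, adjusted p = 0.0481) and the ganglioside synthase B4galnt1 (-1.99, adjusted p = 0.0481) fell, each detected on 2. The laminin Lamc1 fell by 1.87 (adjusted p = 0.0374), and Cxcl10 averaged 4.50 ± 0.07 against 5.99 ± 0.37 (n = 3 each), a log2 fold change of -1.48 (SE 0.19, adjusted p = 0.0098). Copies near-identical to Lilr4b may not be told apart by its probe, which was not checked.

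In camera, 7 of 29 lists shifted in the ligated artery, 0 of them with an estimated correlation, and 12 without 5Aza LCA 1. Cell cycle genes had a median of -0.87 (-0.73 with bounds, adjusted p = 1.58e-09, and adjusted p = 0.28 with an estimated correlation, 3.37e-11 to 0.28 over the alternatives). Birc5 was lower, and 22 of 23 did not pass (11 lower when adjusted over the list alone). Macrophage markers had a median of -1.08 (adjusted p = 1.14e-05, and adjusted p = 0.336 with an estimated correlation, 3.9e-09 to 0.336 over the alternatives). Over all genes 0 of 20 passed, and 2 were lower and 1 higher when adjusted over the list alone. The complement genes C1qa (-2.07, adjusted p = 0.0946) and C1qb (-2.14, adjusted p = 0.102) and the scavenger receptor Cd163 (2.27, adjusted p = 0.123), the only macrophage member with a positive value, came nearest. Of 5 neutrophil markers 0 passed (4 lower and 1 higher when adjusted over the list alone). Their median was -1.31 (-1.13 with bounds, adjusted p = 0.019, and adjusted p = 0.336 with an estimated correlation, 0.00221 to 0.336 over the alternatives). Chil3 (a difference of at least 2.2-fold, adjusted p = 0.0997), Cxcr2 (at least 2.25-fold, adjusted p = 0.105) and S100a9 (-2.64, adjusted p = 0.119) came nearest. Saline LCA 1, with list levels of 5.95 for cell cycle, 7.17 for macrophage and 4.88 for neutrophil genes, lay within the range of 5Aza LCA in each, so these shifts rested on saline LCA 2 and 4. The neutrophil call ended without saline LCA 4 (adjusted p = 0.0522) and without 5Aza LCA 4 (adjusted p = 0.0986).

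The adipocyte list was higher in 5Aza LCA than in saline LCA by a median of 2.45 (2.35 with bounds, adjusted p = 1.14e-05, and adjusted p = 0.28 with an estimated correlation, 2.12e-09 to 0.95 over the alternatives). The 0.95 came with the list's own level as a covariate. Scd1 and Adipoq passed, and 8 members did not (7 higher when adjusted over the list alone). Fibroblast markers shifted by 1.06 (adjusted p = 6.2e-07, and adjusted p = 0.28 with an estimated correlation, 1.61e-08 to 0.28 over the alternatives). Clec3b and Mfap5 (1.74, SE 0.29, adjusted p = 0.0325) were higher, and 15 members did not pass (9 higher when adjusted over the list alone). Atheroprotective genes and the 9 genes recalled from the study shifted as well, both resting on saline LCA 2 and 4. Saline LCA 1 had list levels of 7.89 and 8.14, against 7.86 to 7.91 and 7.87 to 8.15 in 5Aza LCA and 7.33, 7.22 and 7.13, 7.37 in saline LCA 2 and 4. Atheroprotective genes shifted by 0.62 (adjusted p = 0.0149, and adjusted p = 0.336 with an estimated correlation, 0.000249 to 0.336 over the alternatives). Hoxa5, also among the 9 recalled genes and so not independent evidence, passed and 21 did not (8 higher and 2 lower when adjusted over the list alone). The call for atheroprotective genes ended without saline LCA 4 (adjusted p = 0.0522). The 9 genes recalled from the study, not independent evidence on these samples, shifted by 0.41 (adjusted p = 0.0201, and adjusted p = 0.377 with an estimated correlation, 0.00238 to 0.377 over the alternatives). That call ended without saline LCA 2 (adjusted p = 0.14) and without saline LCA 4 (adjusted p = 0.0522). All 9 had positive values, and Hoxa5 alone passed, over all genes and in the list alone. It stood at 7.95 ± 0.08 in 5Aza LCA and 6.79 ± 0.26 in saline LCA (n = 3 each), a log2 fold change of 1.16 (SE 0.22, limma adjusted p = 0.0481, 0.0016 to 0.408 over the alternatives). The value of Cmklr1 turned negative without saline LCA 2 (-0.25), 5Aza LCA 1 (-0.09) or 5Aza LCA 2 (-0.01), and that of Klf3 without 5Aza LCA 4 (-0.07). Endothelial markers as a list were not called (median 0.24, adjusted p = 0.26).

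The lists of DNA methylation, germline, imprinted, p53 and interferon genes were not called in the ligated artery. With 3 pools per group, that does not show that they were unchanged. Genes of the DNA methylation machinery had a median of -0.07 (adjusted p = 0.122), with the DNA repair gene Gadd45a (-1.55, adjusted p = 0.0741) and the maintenance methylation factor Uhrf1 (-1.58, adjusted p = 0.19) nearest. Germline genes, whose promoters are often methylated, had a median of 0.10 (adjusted p = 0.772), imprinted genes 0.22 (adjusted p = 0.269), p53 targets -0.23 (adjusted p = 0.0605) and interferon-stimulated genes 0.08 (adjusted p = 0.683). Of 30 germline genes written, 26 were on the array and only 5 were tested. The others on the array were detected on all 3 samples of no group, so the result says little about silent germline genes.

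The 5Aza calls in the ligated artery rested on single arrays. The count was 2054, with all 49 among them, without saline LCA 1, and 0 without saline LCA 4, 2 without 5Aza LCA 2, 4 without saline LCA 2, 11 without saline RCA 2, 12 without saline RCA 1 or saline RCA 4, 16 without 5Aza RCA 4, 18 without 5Aza LCA 4, 20 without 5Aza RCA 1, 23 without 5Aza LCA 1 and 32 without 5Aza RCA 3. Of the 20 genes with the largest changes, 0 stayed called in limma without saline LCA 4, 1 without 5Aza LCA 2, 2 without saline LCA 2, and 6 to 15 without any other array but saline LCA 1.

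Whether 5Aza moved flow-altered genes the other way was asked by joining both comparisons that share saline LCA. Of the genes called by flow under saline, 29 were also called in the ligated artery under 5Aza with the opposite sign, 15 of them raised by flow and lower under 5Aza and 14 the reverse. Independent lists would share 2.90 such genes. In data simulated with the average flow effect in both treatments and no 5Aza effect, 100 draws gave 2 such genes at most when genes varied independently. When all noise was rebuilt from the arrays' own departures, which ties genes together more tightly than separate samples would, 10 of 100 draws gave 29 or more and 2637 at most. Between these extremes the number could not be told from an effect of the shared samples. The largest were Aspm, Lilr4b, Fgr, Birc5, Ly86, B4galnt1 and Lair1, which flow raised, and Clec3b, Scd1 and Mfap5, which flow lowered. Over all genes, which are not independent replicates, the effects had a covariance of -0.270, and 6 of the 100 draws with tied genes were as low (mean -0.0625). Since saline LCA has 3 samples, it could not be split to remove the sharing. The number of such genes was 1696 without saline LCA 1, 0 without saline LCA 4, 1 without 5Aza LCA 2, 3 without saline LCA 2 and 4 to 19 without any other array.

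The effect of 5Aza without disturbed flow was asked in the unligated artery, where 0 of 10596 genes passed in limma. At unadjusted p under 0.05, 600 genes passed, where 530 are expected by chance, and 1 gene passed with an intensity trend and robust prior, without 5Aza RCA 3 or without saline LCA 1. The genes ranked first, none past the threshold, were Miat (a difference of at least 2.85-fold, adjusted p = 0.0855), the desuccinylase Sirt5 (1.22, adjusted p = 0.3), Fam207a (0.92, adjusted p = 0.32), the antiproteases Serpina1b (-1.09, adjusted p = 0.441) and Serpina1d (-1.09, adjusted p = 0.586) and the nucleoporin Nup98 (-0.97, adjusted p = 0.544). Probes for the Serpina1 genes may not tell these copies apart, which was not checked. All 9 genes recalled from the study had adjusted p of at least 0.857.

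In camera 3 lists were called in the unligated artery of 5Aza mice, 0 of them with an estimated correlation and 0 by fry. The number of calls was 1 without saline RCA 2 or 5Aza RCA 1 and 0 in camera without 5Aza RCA 3. Interferon-stimulated genes had a median of 0.38 (adjusted p = 0.000194, and adjusted p = 0.409 with an estimated correlation, 1.51e-06 to 0.586 over the alternatives). Of 19 values 17 were positive and 0 passed, in the list alone either. The call ended without 5Aza RCA 3 (adjusted p = 0.118). The interferon-induced genes Usp18 (1.19, adjusted p = 0.663) and Ifit1 (1.02, adjusted p = 0.673) and the immunoproteasome subunit Psmb9 (0.61, adjusted p = 0.784) came nearest. Macrophage markers shifted by 0.22 (0.15 with bounds, adjusted p = 0.037, and adjusted p = 0.948 with an estimated correlation, 3.72e-05 to 0.984 over the alternatives). None of the 20 passed, in the list alone either. The antigen presentation genes H2-Aa (1.91, adjusted p = 0.688) and Cd74 (2.01, adjusted p = 0.816) and Aif1 (1.05, adjusted p = 0.847) came nearest. That call ended without saline RCA 1 (adjusted p = 0.38), saline RCA 2 (adjusted p = 0.143), 5Aza RCA 1 (adjusted p = 0.052) and 5Aza RCA 3 (adjusted p = 0.895, median -0.02). Cd74 stood at 9.57, 9.85 and 6.71 and H2-Aa at 9.12, 9.27 and 7.07 in 5Aza RCA 1, 3 and 4, and the erythroid and platelet list moved with them, at 6.26, 6.30 and 5.06 against 5.00 to 5.17 in saline RCA. Extracellular matrix genes shifted by -0.18 over 23 genes (adjusted p = 0.037, and adjusted p = 0.409 with an estimated correlation, 0.00763 to 0.586 over the alternatives). Fibronectin, Fn1 (-0.71, adjusted p = 0.663), the fibulin Fbln2 (-0.45, adjusted p = 0.872) and the basement membrane collagen Col4a1 (-0.43, adjusted p = 0.876) came nearest, and 0 passed, in the list alone either. Without saline RCA 2 the matrix list had adjusted p = 0.0684, without saline RCA 4 0.282, and without 5Aza RCA 1, 3 or 4 0.0555, 0.118 and 0.0799. Methylation machinery genes (median 0.04, adjusted p = 0.929) and germline genes (0.11, adjusted p = 0.777, with 5 tested of 30 written) were not called.

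Whether the flow effect differed between treatments was tested directly as an interaction, in which 0 genes passed in limma. At unadjusted p under 0.05, 1012 genes passed, where 530 are expected by chance, 1 passed with an intensity trend and robust prior, and 847 passed with array weights. The genes ranked first, none past the threshold, were the melanocortin receptor accessory gene Mrap (1.47, adjusted p = 0.206), the protocadherin Pcdhga10 (1.46), Thrsp (2.07), the methyltransferase Mettl6 (-1.70), Lair1 (-1.96) and Aspm (-2.31), the last 5 with adjusted p = 0.228. For the opposite-moving Scd1 the interaction was 2.92 (adjusted p = 0.228) and for Birc5 -1.76 (adjusted p = 0.38), and for Hoxa5 it was 1.14 (adjusted p = 0.371). Without saline LCA 1 the count was 1015.

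In the interaction, camera called 7 of 29 lists, but 0 were called with an estimated correlation and 0 by fry, and 10 of 100 splits of the samples gave as many. The macrophage list's interaction had a median of -1.58 (adjusted p = 1.4e-07, and adjusted p = 0.403 with an estimated correlation, 1.77e-11 to 0.663 over the alternatives). Aif1 stood at -2.11 (adjusted p = 0.371) and H2-Aa at -2.52 (adjusted p = 0.462), neither past. The cell cycle list had -0.79 (adjusted p = 6.46e-07, and adjusted p = 0.403 with an estimated correlation, 1.09e-09 to 0.403 over the alternatives). Its member Aurka stood at -2.24 (adjusted p = 0.446). The adipocyte list had 1.73 (adjusted p = 0.000179, and adjusted p = 0.403 with an estimated correlation, 3.87e-08 to 0.753 over the alternatives, 3 members past when adjusted over the list alone). Adipoq stood at 2.62 (adjusted p = 0.418). The fibroblast list had 0.75 (adjusted p = 0.000155, and adjusted p = 0.403 with an estimated correlation, 1.54e-05 to 0.403 over the alternatives, 1 member past when adjusted over the list alone). Clec3b stood at 2.72 (adjusted p = 0.371).

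The interaction of the HOX list was 0.59 (adjusted p = 0.0354, and adjusted p = 0.403 with an estimated correlation, 0.00553 to 0.403 over the alternatives, 1 member past when adjusted over the list alone). Hoxa3 stood at 0.91 (adjusted p = 0.498). This call ended without saline LCA 1 (adjusted p = 0.302), saline RCA 1 (adjusted p = 0.0676), 5Aza LCA 1 (adjusted p = 0.0607) and 5Aza RCA 1 (adjusted p = 0.0915). The 9 genes recalled from the study, not independent evidence on these samples, had 0.61 (adjusted p = 0.00162, and adjusted p = 0.403 with an estimated correlation, 0.000297 to 0.403 over the alternatives, 2 members past when adjusted over the list alone). Acvrl1 stood at 1.01 (adjusted p = 0.449). The neutrophil list had -1.22 (adjusted p = 0.0423, and adjusted p = 0.441 with an estimated correlation, 0.00208 to 0.441 over the alternatives). That call ended without any of 8 arrays, with adjusted p from 0.0564 without 5Aza RCA 1 to 0.2 without 5Aza LCA 4. Atheroprotective genes were not called (0.66, adjusted p = 0.0524).

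Averaged over both treatments, 1363 genes differed between ligated left and unligated right arteries, 642 higher and 721 lower in the left artery (n = 6 per side). Aif1 led the increases at 4.22 (SE 0.28, limma adjusted p = 1.55e-05), followed by Tyrobp (3.93), Laptm5 (3.63), Lyz1 (3.46), Mmp12 (3.38, adjusted p = 0.000413), the cathepsin Ctss (3.23, adjusted p = 0.00106), Clec7a (3.14), C1qb (3.11), Fcer1g (2.98) and the survival gene Bcl2a1d (2.98), whose near-identical copies may not be told apart. Prrt4 led the decreases at -3.83 (adjusted p = 2.34e-08), and the others named were Klk10 (-3.57), Serpina1a (-2.78), Plekha6 (-2.51), Fndc1 (-2.40), Mfap5 (-2.32), Col4a3 (-2.26), Klk8 (-2.21) and the growth factor Igf2 (-2.21, adjusted p = 0.0113). Col4a3 stood at -2.85 and Klk8 at -2.83 without saline LCA 1. Of the 11 lists called, inflammation genes (median 0.37) held with an estimated correlation (adjusted p = 0.0218). Without saline LCA 1 the count was 3161, without saline LCA 4 or 2 it was 593 and 599, without saline RCA 1 or 2 it was 708 and 748, and without saline RCA 4 it was 822. Without 5Aza LCA 4 it was 759, and without 5Aza RCA 1, 3 or 4 it was 735, 808 and 871.

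Averaged over both arteries, 5Aza changed 0 genes in limma (n = 6 per side). At unadjusted p under 0.05, 1486 genes passed, where 530 are expected by chance, and with array weights 1133 passed at the adjusted threshold. The genes ranked first, none past the threshold and all with adjusted p = 0.0764, were the growth factor binding protein Igfbp4 (0.76), the lectin Cd209f (0.92), the methyltransferase Inmt (1.15), Aspm (-1.34), the transcription factor Tfdp1 (-0.88) and Fn1 (-0.87). Camera called 6 lists and 0 with an estimated correlation: adipocyte (median 1.40), cell cycle (-0.42), extracellular matrix (-0.18), fibroblast (0.48), atheroprotective (0.32) and interferon-stimulated genes (0.22). Without saline LCA 1 the count was 1189, and without 5Aza RCA 1 it was 1.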

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

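In this part, the tests of mislabelling for saline LCA 1 and those of the macrophage, cell cycle and adipocyte patterns were chosen after the result was seen; the test of less immune RNA in saline LCA 1 and the interaction tests were chosen before.

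Camera called 7 lists for a flow effect that differs between 5Aza and saline mice, but 0 were called with an estimated correlation, and 10 of 100 splits of the samples gave as many, so chance cannot be excluded. In medians of the 5Aza effect minus the saline effect, the adipocyte list differed by 1.73, the fibroblast list by 0.75, the genes recalled from the study by 0.61 and the HOX list by 0.59. The macrophage list differed by -1.58, the neutrophil list by -1.22 and the cell cycle list by -0.79. Among 3829 probes without a single gene name, which the gene comparisons left out, 250 passed adjusted p under 0.05 for flow under saline, 140 higher and 110 lower in the ligated artery.

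Saline LCA 1 lay far from saline LCA 2 and 4. An unligated artery under a wrong label is excluded: over the 48 genes called by flow under 5Aza, the slope of its departure from the saline RCA mean on that flow effect was 0.82, against -0.0866 to 0.0769 for single saline RCA samples and 0.867 to 1.03 for the other ligated samples. Less immune-cell RNA with no other difference was tested on list means. Atheroprotective genes of saline LCA 1 lay -0.52 from its endothelial markers, against -1.13 and -1.15 in saline LCA 2 and 4. The largest gap within any other group was 0.22. Those means go against this explanation but do not exclude it, since endothelial markers moved both ways. Pecam1 stood at 10.83 in saline LCA 1 against 9.98 and 10.07 in saline LCA 2 and 4, and Robo4 at 5.74 against 8.22 and 8.02. A ligated artery of a 5Aza mouse under a wrong label stays open. The mean correlation of saline LCA 1 with the 5Aza LCA samples was 0.931, above that of 0.856 with saline LCA 2 and 4. It was no higher than the single correlations of saline LCA 1 with saline RCA reached (0.927 to 0.934). No 5Aza LCA sample reached the macrophage levels of saline LCA 2 and 4. The adipocyte level of 5.55 and the fibroblast level of 7.03 in saline LCA 1 both lay below the lowest 5Aza LCA samples (6.75 and 7.37). A weaker response to the ligation in that pool also stays open and was not tested.

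The macrophage and cell cycle lists were lower in 5Aza LCA than in saline LCA, a difference carried by saline LCA 2 and 4 (cell cycle levels of 7.29 and 6.78, macrophage levels of 8.91 and 9.13), since saline LCA 1 (5.95 and 7.17) lay within the range of 5Aza LCA. Quantile normalization is excluded as the sole source of these camera calls, since the larger of both adjusted p-values was 2.64e-06 with median scaling. Background correction was the same in both, and other ways of scaling were not tested. Both calls rest on the preset correlation: with an estimated one, adjusted p was 0.336 for the macrophage list and 0.28 for the cell cycle list. Fewer macrophages in the flushed RNA may account for the macrophage list, as 95% of its 20 members were lower. Whether they also account for the cell cycle list stays open: with the macrophage level as a covariate it kept its call here (median -0.60, adjusted p = 1.47e-06, over a range of 3.37e-11 to 0.28 for all its alternatives), but not in the interaction (-0.30, adjusted p = 0.068) or for flow under saline (-0.25, adjusted p = 0.336), and 83.6% of that level's variance lay between the groups. A difference by treatment in the artery's own cells stays open too and was not tested.

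The adipocyte list was higher in 5Aza LCA than in saline LCA, a call that rests on the preset correlation (adjusted p = 0.28 with an estimated correlation). Within that test no single 5Aza LCA array decided it, since the largest adjusted p without any 1 of them was 0.000577, with medians of 2.73, 2.54 and 1.63. Fat tissue carried into the flush cannot be told apart from a change of expression: 90% of the 10 markers were higher, and their departures from the group means correlated at 0.314 on average, against 0.632 for macrophage markers. Pck1, a gene of fat cells, stood at 6.88, 8.59 and 10.11 in 5Aza LCA 1, 2 and 4, and Cox8b, a gene of brown fat, at 4.61, 6.50 and 9.26. Neither passed in limma (adjusted p = 0.0765 and 0.141). The members Lipe, Pparg and Lpl changed least, with log2 fold changes of -0.01, 0.15 and 0.69. A difference between treatments in the artery itself stays open.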

How the results depend on the processing

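The macrophage and adipocyte covariates in this part were chosen after the data were seen; the other alternatives were chosen before. Where no cause is named, the cause was not tested.

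Of the values of named genes under alternatives other than a left-out array or a covariate, 3228 of 3653 kept their direction and their side of the threshold, 352 lost a call, 73 gained one and 0 changed direction. Of the list results outside left-out arrays, 263 kept both, 121 lost the call and 6 changed direction; with 1 array left out 419 kept both and 49 lost the call. With 1 array left out, 2434 of 3024 values of named genes kept both, 535 lost a call, 50 gained one and 5 changed direction.

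For flow under saline (1227 genes), the count was 616 with no detection filter, 135 with only the compared groups in the fit, 3744 with array weights and 179 to 3114 with 1 array left out. For flow under 5Aza (48), it was 78 with an intensity trend and robust prior, 157 with array weights and 4 to 286 with 1 array left out. With the deposited normalized values 58 genes passed, 24 higher and 34 lower. For 5Aza in the ligated artery (49), it was 20 with no filter, 0 with only the compared groups, 104 with the trend and robust prior, 2258 with array weights and 0 to 2054 with 1 array left out. For 5Aza in the unligated artery (0), it was 1 with the trend and robust prior and 0 to 1 with 1 array left out. For the interaction (0), it was 1 with no filter, 1 with the trend and robust prior, 847 with array weights and 0 to 1015 with 1 array left out. For average flow (1363), it was 897 with no filter, 2133 when every probe was counted, 3395 with array weights and 593 to 3161 with 1 array left out. For average 5Aza (0), it was 5 without background correction, 5 with the deposited normalized values, 5 with no filter, 20 with the trend and robust prior, 1133 with array weights and 0 to 1189 with 1 array left out. For opposite calls (29), it was 10 with no filter, 0 with only the compared groups, 70 with the trend and robust prior, 1843 with array weights and 0 to 1696 with 1 array left out. No filter raised the genes tested to 19057, fits with only the compared groups hold 6 of the 12 samples, and counting every probe adds several per gene.

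The values gave at most a weak sign that equal numbers pair the samples. Departures from group means of saline left and right arteries correlated at 0.0331 to 0.0561 with the same number and at -0.067 to 0.0228 with different numbers. Every saline pair with the same number thus lay above the rest, but the values were small. In 5Aza arteries, by description number, the correlations were -0.0285 to 0.0182 with the same number and -0.019 to 0.0476 with different numbers. A random block had a consensus correlation of 0.0185. With title numbers as a fixed block within treatments, the count was 276 for flow under saline, 4 for flow under 5Aza and 295 for average flow. With title numbers across all groups it was 702, 13 and 536, and 0 for 5Aza in the ligated artery and for opposite calls. With description numbers across groups it was 21 for 5Aza in the ligated artery and 13 for opposite calls. Chips as a block were not run, since the chip of each sample was not given in the sources used here.

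Lists called for flow under saline (10) came to 1 with an estimated correlation and 8 to 11 with 1 array left out; for flow under 5Aza (12), to 0 with an estimated correlation, 2 with fry and 10 to 13 with 1 array left out. For 5Aza in the ligated artery (7), they came to 0 with an estimated correlation and 5 to 12 with 1 array left out. For 5Aza in the unligated artery (3), they came to 0 with an estimated correlation, 0 with fry, 1 with title numbers across groups as a block and 0 to 4 with 1 array left out. For the interaction (7), they came to 0 with an estimated correlation, 0 with fry, 11 with no filter and 5 to 9 with 1 array left out. For average flow (11), they came to 1 with an estimated correlation, 17 with fry and 10 to 13 with 1 array left out. For average 5Aza (6), they came to 0 with an estimated correlation, 0 with fry, 10 with no filter and 5 to 9 with 1 array left out.

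With the macrophage level as a covariate, 2 genes passed for flow under saline, 4 for flow under 5Aza, 9 for 5Aza in the ligated artery, 3 for average flow and 0 as opposite calls, and 4, 5 and 2 lists for flow under saline, flow under 5Aza and the interaction and 5 for average flow. With the adipocyte level, 2 genes passed for flow under 5Aza, 0 for 5Aza in the ligated artery, 167 for average flow and 0 as opposite calls, and 7 lists for flow under 5Aza and 1 for 5Aza in the unligated artery. The flow effects correlated at 0.698 and 0.292 with these covariates and at 0.493 to 0.58 with 1 array left out. The groups account for 83.6% of the variance of the macrophage level and 74.7% of that of the adipocyte level, so either covariate removes much of the group differences.

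With the macrophage covariate, medians changed sign for cell cycle (-0.25), neutrophil (-0.15) and oxidative stress (-0.11) in flow under saline and for macrophage markers (-0.23) for 5Aza in the unligated artery, and the test of oxidative stress in flow under 5Aza turned downward at a median of 0.11; with the adipocyte covariate, the respiratory chain changed to -0.17 in flow under 5Aza.

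Named genes reversed with the macrophage covariate in flow under saline were Hbb-bs (-0.24), Mmp13 (-0.42), Clec10a (-0.27), Lyz1 (-1.07), Klk8 (0.42), Cmklr1 (1.71), Pkp4 (0.02), Spry2 (0.06), Zfp46 (0.17), Clec3b (0.33), Aurka (-0.56), Top2a (-0.28), Pf4 (-1.48), Cxcr2 (-0.30), Chil3 (-0.34), Cybb (-0.35), Txnrd1 (-0.28), Sod3 (0.60), Bmpr2 (0.19), Smad7 (0.09) and Uhrf1 (-0.95). In average flow they were Lyz1 (-0.43), Col4a3 (0.21), Klk8 (0.63) and Igf2 (0.64). In flow under 5Aza they were Cmklr1 (0.81), Pkp4 (0.19), Spry2 (0.20), Zfp46 (0.13), Aspm (-0.26), Lilr4b (-0.71), Fgr (-0.56), Birc5 (-0.64), Ly86 (-0.72), B4galnt1 (-0.57), Lair1 (-0.43) and Cybb (-0.08). They were Cmklr1 (-0.70) and Zfp46 (-0.01) for 5Aza in the ligated artery, and Cmklr1 (-0.90) and Zfp46 (-0.04) in the interaction.

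With the adipocyte covariate, values reversed for Cmklr1 (0.38), Lilr4b (-0.19), Birc5 (-0.13), Ly86 (-0.16), B4galnt1 (-0.18), Uqcrc1 (0) and Gpx3 (-0.01) in flow under 5Aza and for Klf3 (-0.43) for 5Aza in the ligated artery. With 1 array left out, the value for 5Aza in the ligated artery ran from -0.25 to 1.03 for Cmklr1 and from -0.07 to 0.26 for Klf3. Signal over background limits the dim genes: probes under detection give only bounds, and their calls depend on the filter.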

Other observations

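In this part, the splits of the ligated samples and the simulations for opposite calls and the genes of lists too small to test were chosen after the results were seen; the other tests were chosen before the data were examined.

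Single genes of matrix turnover passed with flow under saline, although neither of their lists was called. The macrophage elastase Mmp12 (3.43, SE 0.52, limma adjusted p = 0.0047), the cathepsin Ctss (3.73, SE 0.57, adjusted p = 0.00471) and Mmp13 rose, whereas the protease inhibitor Timp2 fell by 0.92 (SE 0.16, adjusted p = 0.00883). The list of 18 matrix proteases was not called (median 0.33, adjusted p = 0.0752), with 3 higher, 1 lower and 14 not past (4 higher and 2 lower when adjusted over the list alone). Among 23 extracellular matrix genes, the collagens Col1a1 (1.65, SE 0.33, adjusted p = 0.0147) and Col8a1 (2.01, SE 0.44, adjusted p = 0.0194) rose, and elastin, Eln (-1.33, SE 0.24, adjusted p = 0.01), and the proteoglycan Bgn (-0.76, SE 0.17, adjusted p = 0.019) fell. That list was not called either (median 0.35, adjusted p = 0.139), with 3 higher, 3 lower and 17 not past (5 higher and 3 lower when adjusted over the list alone).

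The list of 20 BMP and TGF-beta genes was not called with flow under saline, but 5 members passed, all lower. They were the receptors Acvrl1 (-1.28, SE 0.23, limma adjusted p = 0.00953), Bmpr2 (-1.11, SE 0.26, adjusted p = 0.0253) and Acvr1, the last named after its values were seen, the latent TGF-beta binding protein Ltbp4 (-0.93, SE 0.19, adjusted p = 0.0147) and the inhibitory Smad7 (-1.11, SE 0.28, adjusted p = 0.0299). The list had a median of 0.06, a mean of -0.10 and a downward test that did not pass (adjusted p = 0.559), with 15 members not past (1 higher and 5 lower when adjusted over the list alone). Of 10 genes of the DNA methylation machinery, the demethylation-linked Gadd45a (2.15, SE 0.33, adjusted p = 0.00526) and the maintenance factor Uhrf1 (2.11, SE 0.59, adjusted p = 0.0426) rose and the methyltransferase Dnmt3a fell by 0.90 (SE 0.17, adjusted p = 0.0106), with the list not called (median 0.17, adjusted p = 0.556). Of 16 smooth muscle markers, Cald1 (1.40, SE 0.32, adjusted p = 0.0222) and the light chain Myl9 (1.55, SE 0.44, adjusted p = 0.0434) rose and the calcium pump regulator Pln fell by 1.51 (SE 0.27, adjusted p = 0.00927), with the list not called (median 0.35, adjusted p = 0.102). In lists too small to test, the epithelial genes Cdh1 (2.36, adjusted p = 0.00846) and Krt18 (1.56, adjusted p = 0.0219) rose and the nerve genes Stmn2 (-2.63, adjusted p = 0.00106) and Mal (-1.30, adjusted p = 0.0274) fell. Their adjusted p over the alternatives reached 0.87 for Cdh1, 0.862 for Krt18, 0.736 for Stmn2 and 0.992 for Mal.

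For comparisons of 3 with 3 samples, the 10 possible splits are too few for a share under 0.05. For flow under saline, 1 of the 10 splits, the real one, gave 1227 genes or more (highest other 0), and 1 gave 10 lists or more (highest other 7). For flow under 5Aza, 1 of 10 gave 48 genes (highest other 0) and 1 gave 12 lists (highest other 6). For 5Aza in the ligated artery, 2 of 10 gave 49 genes or more (highest other 281) and 3 gave 7 lists or more (highest other 8). The split with 281 genes set 5Aza LCA 4 with saline LCA 2 and 4 against the remaining ligated samples, which points to a structure of these samples that the treatment does not follow. For 5Aza in the unligated artery, 1 of 10 gave 600 genes at unadjusted p under 0.05 (highest other 411), and 3 gave 3 lists or more (highest other 4).

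Across 100 splits drawn for the remaining results, only the real one gave 1363 genes for average flow (highest other 66). The same held for the correlation of the flow effects of 0.575 (highest other 0.46). With 1 of 100 draws, chance is unlikely for both but not excluded. A split that only swaps the 5Aza sides would give the same correlation with the opposite sign, and it was not among those drawn. For average 5Aza, 3 splits, the real one among them, gave 1486 genes or more at unadjusted p under 0.05 (highest other 1545). Since other splits exceeded the real one and 0 genes passed the adjusted threshold, chance is not excluded there. For opposite calls, 2 of 100 draws over the saline and 5Aza LCA samples gave 29 or more (highest other 306), but such draws also break up the flow effect and so do not test 5Aza. Regrouping the ligated samples alone, 1 of 10 splits, the real one, gave 29 (highest other 2), too few splits for a share under 0.05. In simulations that keep the flow effect, 0 of 100 draws gave 29 or more with independent genes and 10 of 100 with genes tied together more tightly than separate samples would, so an effect of the shared samples stays open. The draw with 306 points to a structure of the samples. Chance cannot be excluded for the interaction, where 27 splits gave 1012 genes or more at unadjusted p under 0.05 (highest other 1638) and 10 gave 7 lists or more (highest other 11). Nor can it be excluded for the lists of average flow (6 splits with 11 or more, highest other 14) and of average 5Aza (22 splits with 6 or more, highest other 11).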
